A study of Mus musculus with 29 samples.

How the data were processed

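The study compared hypothalamus RNA of 8-week-old mice given tumour cells in 100 µl PBS with that of mice given PBS, on in-house printed 2-colour oligonucleotide arrays. Per the labels, arrays of a replicate share 1 pair of RNAs, some with dyes exchanged, and poly(A) RNA was used in replicates 1 and 2 of each time and total RNA in the others. There were 10, 10 and 9 arrays at 18, 72 and 192 h. Each array has 3 scanner files, 87 in all, taken at different brightness; scanner, gain and image software are not given in the sources used here.

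Per the file headers, the spot intensities are already corrected for local background, and background intensities are listed beside them. A deposited saturation factor, a fraction between 0 and 1, tells how much of a spot is free of saturation. The authors' deposited value tables, treated here as a score, hold a log ratio per spot. They followed tumour over PBS in all 29 columns (correlation across spots 0.696 to 0.944) and are centred, with column medians from -0.008 to 0.011. Their log base stays unknown, since their spread was 0.451 to 0.885 of that of the log2 ratios here.

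Ratios were computed in R 4.3.3 with limma 3.58.1. Spots that the files mark as not measured, saturated or not above 0 in either channel were left out, as planned. Keeping saturated spots is an alternative chosen after seeing the data. Each scan was normalized by loess (span 0.3, 4 iterations) and the scans averaged. The dye effect of each probe, the mean Cy5 over Cy3 ratio of the 7 replicates labelled in both orientations, was subtracted (SD 0.30 log2 over 7938 probes). Ratios were turned to tumour over PBS and averaged per replicate. The labels list Cy3 as channel 1 and Cy5 as channel 2, and the scanner files call the channels A and B; the direction assumes the same order. The authors' tables turn sign with the labelled orientation, which bears on the order but does not settle it.

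Probe names came from the platform annotation supplied for each of the 5 array prints. It gives 9008 accessions on all prints, of which 11 have several symbols and were not named, and 8726 genes. Of the accessions 8909 matched a current gene record. Between 994 and 1002 spots per print are not listed there and were not tested. On prints 3 to 5 mean intensities matched by accession correlated at 0.63 to 0.67, but at 0.06 to 0.15 between prints 1 or 2 and the others. Accessions spotted at 2 places correlated at -0.03 and -0.04 on prints 1 and 2 and at 0.56, 0.49 and 0.64 on prints 3 to 5. Gene results therefore use prints 3 to 5 only, a departure from the design of 13 replicates that was fixed before the data were examined; that design is given as an alternative. The design had also foreseen normexp with an offset of 50, which was replaced because the intensities are already corrected.

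A gene was represented by its brightest probe and tested at a time if all 3 replicates had a value. One linear model per gene with a mean for each time was fitted by limma with empirical Bayes moderation, the spread being shared over 5184 genes (prior degrees of freedom 6.87). An earlier version shared the spread over all measured genes; it was replaced after its list results had been seen, and called 4 lists at 192 h where the present one calls 2. Tests were two-sided with Benjamini-Hochberg adjustment within a comparison. The 27 gene lists, 11 of them markers of cell types or regions, were fixed beforehand and tested by cameraPR with a preset correlation of 0.01 where 5 or more genes were measured. Camera with an estimated correlation and fry were fitted on the replicates of the times compared alone, and the correlation and these replicates were also changed one at a time. The sign of the test, of the mean or of the median differed at 18 h for feeding, immediate early and proteasome genes, at 72 h for feeding, immediate early, GABA and glutamate and monoamine genes, and at 192 h for cholesterol synthesis, clock, neuronal and neighbouring-region genes. Of the lists 18 could be tested at some time, and 9 could not, with at most 4 measured genes. The latter were markers of microglia and macrophages, blood cells, endothelial and mural cells, choroid plexus and ependyma, pituitary, meninges and fibroblasts and hypothalamic regional identity, and interferon-response and cell cycle genes.

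Named genes followed a rule fixed beforehand. It takes up to 10 genes past the test in each direction with 1 sign in every replicate, filled to 5 with the smallest p of that sign where fewer pass. It also takes up to 4 members of a list, the 10 smallest p between times and 8 peptide genes. Of list members, the text names those of lists with an unadjusted p under 0.1 and those with an own unadjusted p under 0.05, a narrowing chosen after the values were seen. Values are means ± SD of the replicates.

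The scripts were tested on simulated ratios with the real missing values. A log2 change of 1 was recovered for 89.5% of changed genes at 18 h (1441 genes), 83.2% at 72 h (3593), 81% at 192 h (3276) and 100% over the 3 times (737). The simulation draws independent noise per gene. It planted many changes at once, with 57, 125, 200 and 44 changed genes among those tested, which eases the adjusted threshold. Recovery of only a few changed genes was not simulated. Alternatives covered background, normalization, dye, scans, RNA kind, prints, probes, saturation, spread, the list test and each left-out replicate. Figures were drawn with matplotlib 3.10.9.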

Results

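The hypothalamus of female BALB/c mice was profiled 18, 72 and 192 h after subcutaneous injection of 100000 4T-1 cells, a transplantable mouse mammary carcinoma line, or of PBS alone. Each array was a 2-colour hybridization of tumour RNA against PBS RNA, so every value below is a ratio within an array. The series holds 29 arrays of 13 biological replicates, 5 at 18 h and 4 each at 72 and 192 h. Genes were named on 16 of these arrays, from 9 replicates with 3 at each time. On the other 13 arrays the given probe names matched the intensities of the spots poorly. Between 14.8% and 83.5% of the spots of an array gave a usable ratio, and the median standard error of a log2 ratio was 0.17 at each time, with 3 replicates. The labels do not say whether RNA of several animals was pooled in a replicate, so p-values measure the spread between these samples only.

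The comparison at 18 h asked which hypothalamic genes differed soon after the tumour cells were injected. Ratios are log2 of tumour over PBS; this direction is likely rather than settled, since it rests on the labelled dyes and on channel order, and the scanner files do not name the dyes. No gene passed the test (limma, adjusted p 0.05; 1441 genes tested), and 86 genes had an unadjusted p under 0.05, against 72.05 that chance would give. The 5 genes of smallest p with higher ratios in all 3 replicates, none past the test, were Rasd1, Lasp1, Top3a, Odc1 and Vps4a. Rasd1, a Ras-related protein induced by dexamethasone, had a log2 ratio of 0.59 ± 0.17 (SD, n = 3), a 1.51-fold difference. Odc1, which encodes ornithine decarboxylase of polyamine synthesis, had 0.49 ± 0.45. Lasp1, an actin-binding protein gene, had 0.50 ± 0.04, Top3a, a DNA topoisomerase gene, 0.51 ± 0.16 and Vps4a, an ATPase gene of endosomal sorting, 0.35 ± 0.17.

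On the lower side at 18 h stood Chga, Adam9, Lta4h, Tmeff2 and Ncoa1, also none past the test (smallest adjusted p 0.409 by limma). Chga, which encodes chromogranin A of dense-core secretory granules, had the lowest log2 ratio of these, -1.06 ± 0.92. Adam9, a membrane metalloprotease gene, had -0.89 ± 0.69, and Lta4h, the gene of leukotriene A4 hydrolase, -0.78 ± 0.46. Tmeff2 had -0.74 ± 0.45 and Ncoa1, a coactivator of nuclear receptors, -0.64 ± 0.41. Of the 86 genes with an unadjusted p under 0.05, 80 were lower and 6 higher, and the median over all tested genes was -0.09. This median was -0.02 without replicate 3, whose own mean over all genes was -0.21 against -0.05 and -0.01 in replicates 4 and 5, and -0.02 without replicate 5, where more genes were tested. With median centring it was -0.16, and with loess within print blocks -0.02.

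Of the gene lists, 7 had 5 or more measured members at 18 h and none was shifted. Over all genes tested at this time only 31.4% were positive, against which the counts below are to be read. Ribosomal protein genes came closest (12 of 19 positive, mean log2 ratio 0.01, adjusted p 0.197, higher relative to other genes). Rps27 had 0.26 ± 0.24 and Rpl37 0.14 ± 0.07, and both were below 0 with median centring and by the authors' value table. Rps6 had -0.16 ± 0.15 and Rps25 -0.12 ± 0.06, and both were above 0 under normexp. Of the oxidative phosphorylation genes 23 of 27 were negative (mean -0.12, adjusted p 0.432), among them Cox8a, a cytochrome c oxidase subunit gene, at -0.38 ± 0.19. Feeding neuropeptides and receptors (5 of 9 positive), heat shock and unfolded protein response genes (3 of 5), immediate early genes (2 of 5), proteasome subunit genes (3 of 8) and synaptic vesicle genes (4 of 6) did not pass.

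At 72 h no gene passed the test either (limma; 3593 genes tested, smallest adjusted p 0.439), with 200 genes at an unadjusted p under 0.05 against 179.65 by chance. With normexp background correction, the setting first planned, 9 genes passed, 2 higher and 7 lower. The highest ratios among the genes of smallest p were those of Tm4sf1, a tetraspanin-like membrane protein gene, at 1.80 ± 1.44 (SD, n = 3), and of Dbf4, which encodes the regulatory subunit of the Cdc7 kinase, a 2.83-fold difference with an SD of 0.60 on the log2 scale. Cd37, a leukocyte tetraspanin gene, had 0.92 ± 0.32, Luc7l 0.70 ± 0.39 and Tmem50b 0.68 ± 0.37, the last at -0.03 with dye orientation as a covariate. Tm4sf1 passed only when replicate 3 was left out, at a log2 ratio of 2.62, and stood at 0.11 without dye correction. Cd37 was among the genes past the test under normexp, at 0.74.

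The 5 lower genes of smallest p at 72 h were Cfap298, Mov10l1, Prokr1, Gnat1 and C5ar1, negative in all 3 replicates. Cfap298, a gene of ciliary function, had -0.90 ± 0.17, and C5ar1, the receptor of complement C5a, -0.81 ± 0.22. Prokr1, a prokineticin receptor gene, had -0.82 ± 0.17, Mov10l1, a helicase gene of the piRNA pathway, -0.83 ± 0.12 and Gnat1, rod transducin alpha, -0.79 ± 0.09. Prokr1 passed under normexp, at -0.96. Without dye correction Mov10l1 and Prokr1 stood above 0, at 0.11 and 0.06.

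None of the 17 lists tested at 72 h was shifted (smallest adjusted p 0.487). Ribosomal protein genes were positive for 18 of 23 members (mean 0.09), with Rps15 at 0.19 ± 0.03, below 0 with median centring, and Rpl10a, Rps4x and Rpl24 between 0.26 and 0.29. Proteasome subunit genes were positive for 11 of 13 (mean 0.11), with Psmb6 at 0.33 ± 0.23, Psmb3 at 0.28 ± 0.30, Psmd2 at 0.15 ± 0.08 and Psmd4 at 0.26 ± 0.39, the last of them below 0 under normexp. Cytokine and acute inflammatory genes were positive for 8 of 10 (mean 0.05, adjusted p 0.780). Abat, the enzyme that degrades GABA, had -0.47 ± 0.28 and stood at 0.08 without dye correction, and Dnajb5, a heat shock cochaperone gene, had 0.45 ± 0.28. Sv2a, a synaptic vesicle protein gene, had 0.51 ± 0.53 and -0.17 with loess within print blocks. Astrocyte markers (5 of 5 positive), neuronal markers (7 of 10), oligodendrocyte and myelin markers (2 of 5) and markers of neighbouring brain regions (7 of 9) did not pass. Neither did feeding (5 of 11), oxidative phosphorylation (18 of 31), hormone (3 of 5), immediate early (5 of 10), clock (1 of 5), cholesterol synthesis (3 of 5), GABA and glutamate (7 of 9), heat shock (5 of 8), monoamine (3 of 5) and synaptic vesicle genes (7 of 13).

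At 192 h genes of oxidative phosphorylation and a list of hormone and other neurosecretory genes were higher as groups relative to other genes, by small amounts. Oxidative phosphorylation genes, which encode the respiratory chain and ATP synthase of mitochondria, were positive for 28 of 35 members, with a mean log2 ratio of 0.10 (cameraPR, adjusted p 0.0148). Releasing and neurohypophysial hormone genes were positive for 8 of 9 members, with a mean of 0.19 (cameraPR, adjusted p 0.0373). Besides hormones, this list holds genes of secretory granules and of monoamine synthesis and transport. Under normexp, the setting first planned, it did not pass (cameraPR, adjusted p 0.0635). By camera on the 3 replicates of this time neither passed (adjusted p = 0.664 for both with an estimated correlation). With only the correlation changed, which was estimated at 0.115 and -0.00892, the adjusted p by cameraPR was 0.264 and 0.0523. The negative estimate was set to 0, and the hormone list then had an unadjusted p of 0.00307, against 0.00439 in the main test. Its adjusted p rose through its rank among the lists, not through the correlation. With only the replicates changed the adjusted p by camera was 0.0127 for both. Fry, which tests a list against no change and not against other genes, gave an adjusted p of 0.680 and 0.554. No member of either list passed the test by itself, adjusted over the list alone or over all genes.

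The members of smallest p among the oxidative phosphorylation genes were Atp5j at 0.28 ± 0.25 (SD, n = 3), Uqcrc1 at 0.26 ± 0.20, Uqcrb at 0.27 ± 0.40 and Ndufs4 at 0.26 ± 0.28. Of the hormone list, Avp, which encodes vasopressin, had 0.36 ± 0.32 and was above 0 in all 3 replicates. Scg3, a granin gene of secretory granules, had 0.30 ± 0.29, Adcyap1, which encodes the peptide PACAP, 0.28 ± 0.47 and Gnrh1, gonadotropin-releasing hormone, -0.25 ± 0.17. The oxidative phosphorylation mean was 0.15 in replicate 1 and 0.17 in replicate 3 but -0.03 in replicate 4, and the hormone mean was 0.30, 0.19 and 0.07. Replicate 1 rests on 1 named array, of poly(A) RNA with tumour in Cy5 only, so its values depend on the subtracted dye effect. Probes of the other replicates can also rest on 1 orientation. In replicate 3, 2474 probes had a ratio on both arrays, while at least 4671 had a value in the replicate. With dye orientation as a covariate neither list passed (cameraPR, adjusted p 0.141 and 0.303). Replicate 4 is the 192 h replicate on print 5. On print 5 alone, where it stands by itself and is assumed to vary like the other times, neither list was shifted (adjusted p 0.955 for both). Without replicate 1 or without replicate 3 no list passed, and without replicate 4 there were 4. Without replicates 1, 3 and 4 in turn, the oxidative phosphorylation mean was 0.0555, 0.0638 and 0.153. The hormone mean was then 0.104, 0.121 and 0.248, with the tested genes differing somewhat. Each 192 h replicate is on a print of its own, so a random block for print (adjusted p 0.0140 and 0.0395) cannot separate print from replicate. In replicate 1 markers of oligodendrocytes and myelin had a mean of 0.34 and those of astrocytes 0.27, against 0.02 and -0.12 in replicate 3 and 0.02 and -0.00338 in replicate 4.

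**Figure D1:**
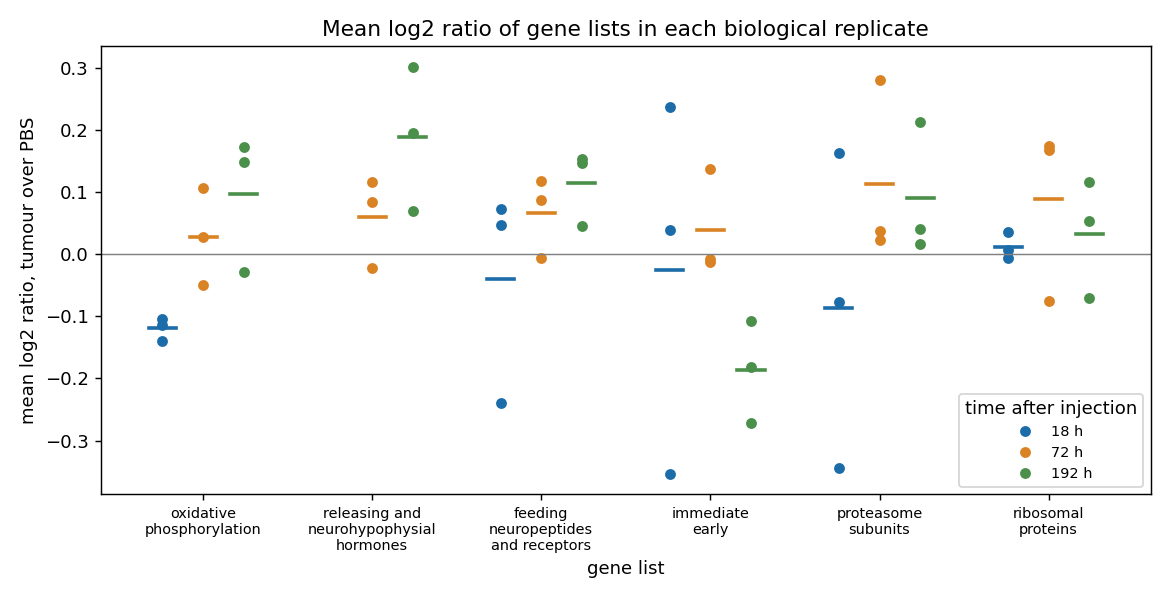
Mean log2 ratio of tumour over PBS (y axis) of 6 gene lists (x axis) in each biological replicate at 18, 72 and 192 h; points are replicates and short lines the means over replicates, and a list with fewer than 5 measured genes at a time has no points there. The oxidative phosphorylation mean was 0.15 and 0.17 in replicates 1 and 3 at 192 h and -0.03 in replicate 4.

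The other 15 lists did not pass at 192 h. Immediate early genes, transcribed within minutes of neuronal activation, were negative for 7 of 9 members (mean -0.19, adjusted p 0.0514), with Egr4 at -0.58 ± 0.43, Nr4a3 at -0.48 ± 0.73, Fosb at -0.33 ± 0.58 and Klf2 at -0.20 ± 0.31. Feeding neuropeptides and receptors were positive for 9 of 12 (mean 0.12, adjusted p 0.0555), with Insr, the insulin receptor gene, at 0.35 ± 0.13, Cartpt at 0.30 ± 0.28, Hcrt, which encodes orexin, at 0.30 ± 0.33 and Pnoc at 0.25 ± 0.26. Proteasome subunit genes were positive for 9 of 13 (adjusted p 0.123), with Psmd3 at 0.32 ± 0.25, Psmc1 at 0.17 ± 0.09, Psmd13 at 0.26 ± 0.29 and Psmc5 at 0.18 ± 0.19, of which Psmd13 was below 0 under normexp and Psmc5 with the third scan alone. Of the cytokine and acute inflammatory genes 5 of 6 were negative (adjusted p 0.409), with the chemokine gene Ccl4 at -0.70 ± 0.56 and the adhesion molecule gene Vcam1 at 0.40 ± 0.19. Markers of other cell types and regions did not pass, with astrocytes positive for 5 of 6 (mean 0.05), oligodendrocytes and myelin for 5 of 6 (mean 0.12), neurons for 3 of 8 and neighbouring brain regions for 4 of 6. Ribosomal protein (12 of 23 positive), heat shock (9 of 10), synaptic vesicle (6 of 11), GABA and glutamate (8 of 13), glucocorticoid-responsive (5 of 7), cholesterol synthesis (4 of 7) and clock genes (2 of 5) did not pass.

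No single gene passed the test at 192 h (limma; 3276 genes tested, smallest adjusted p 0.606), with 91 genes at an unadjusted p under 0.05 against 163.8 by chance. The higher genes of smallest p were Ap2a2, a clathrin adaptor gene, at 0.77 ± 0.52 (SD, n = 3), Ecrg4 at 0.71 ± 0.50, the transcription factor gene Foxb1 at 0.54 ± 0.38, Fasn, the fatty acid synthase gene, at 0.49 ± 0.28 and Oxa1l, an insertase gene of the mitochondrial inner membrane, at 0.44 ± 0.09. The lower ones were Gpcpd1 at -1.33 ± 1.30, 3200001D21Rik at -0.89 ± 0.59, the peptidase gene Tpp2 at -0.79 ± 0.13, Cebpa, a transcription factor gene, at -0.61 ± 0.37 and Bak1, a gene of the mitochondrial pathway of apoptosis, at -0.57 ± 0.39. With RNA kind as a term 2 genes passed, Gpcpd1 at -1.69 and Jam2, named after its value was seen, at -1.99. With dye orientation as a covariate Gpcpd1 stood at 0.03 and 3200001D21Rik at 0.56. Replicate 1 of 72 h and of 192 h are the only named replicates of poly(A) RNA, each on 1 named array with tumour in Cy5. RNA kind, dye orientation and the single array therefore cannot be told apart, and these settings are not separate checks.

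**Figure D2:**
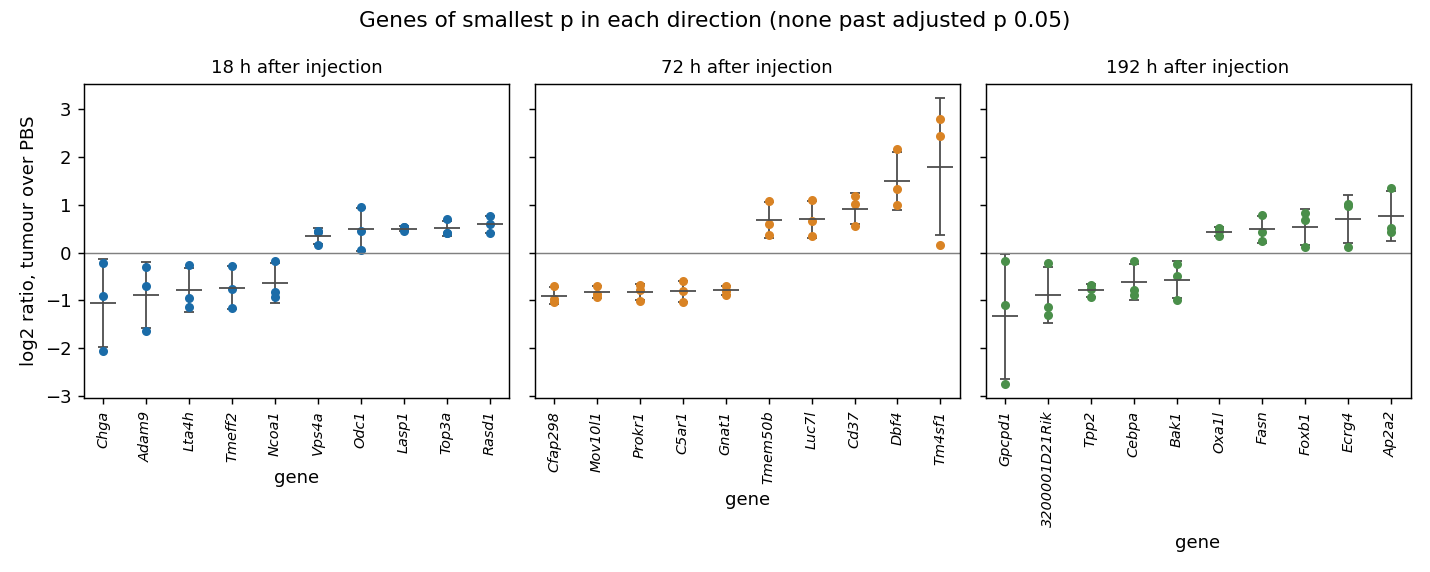
Log2 ratio of tumour over PBS (y axis) of the 5 higher and 5 lower genes of smallest p (x axis) at 18, 72 and 192 h; points are the 3 biological replicates, the horizontal mark is their mean and bars are the SD. None of these genes passed an adjusted p of 0.05; Tm4sf1 at 72 h has the highest mean, 1.80, and Gpcpd1 at 192 h the lowest, -1.33.

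Of the 8 hypothalamic peptide genes chosen beforehand, Oxt, which encodes oxytocin, was measured at every time, with log2 ratios of 0.10 ± 0.17 at 18 h, 0.17 ± 0.37 at 72 h and 0.17 ± 0.27 at 192 h. Hcrt had -0.05 ± 0.31 at 72 h and 0.30 ± 0.33 at 192 h. None of these values passed the test, and the sign of Hcrt at 72 h and of Oxt at 18 h turned with median centring. Avp reached 3 replicates at 192 h only. Pmch had no usable value, and Npy, Agrp, Pomc and Crh were not analysed here.

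A change shared by all times was tested on the 737 genes measured in all 9 replicates. No gene passed (limma, smallest adjusted p 0.428), and 23 had an unadjusted p under 0.05. Tumour over PBS profiles of different replicates were nearly unrelated across genes, which are not independent replicates: the median correlation over 9 pairs of the same time was 0.03, from -0.13 to 0.20, and over 27 pairs of different times -0.00133, from -0.32 to 0.22.

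Differences between the times were tested directly. No gene of 737 passed the moderated F-test of limma (smallest adjusted p 0.994), and 17 had an unadjusted p under 0.05. None passed in a pairwise contrast, with 51 of 998 genes at an unadjusted p under 0.05 for 72 against 18 h, 33 of 973 for 192 against 18 h and 40 of 1892 for 192 against 72 h. The gene of smallest p was Tmeff2, at -0.74 ± 0.45 at 18 h, 0.19 ± 0.13 at 72 h and 0.27 ± 0.10 at 192 h. Tpp2 had 0.05 ± 0.19, -0.36 ± 0.28 and -0.79 ± 0.13 at these times, and Dbf4 -0.02 ± 0.09 at 18 h and 0.43 ± 0.95 at 192 h, beside its 2.83-fold difference at 72 h. With the replicate number as a block Tmeff2 and Dbf4 passed the F-test (limma, adjusted p 0.0384 for both), and 6 genes passed for 192 against 18 h. Under normexp 1 gene passed for 192 against 72 h. The other genes among the 10 of smallest p were Ncoa1, Nmd3, Snx5, Aldh6a1, Atg3, Cyp4f16 and Dpysl5, of which all but Cyp4f16 had their lowest mean at 18 h. Of the gene lists, tested between times after the data were seen, none of 4 passed for 72 or 192 against 18 h. For 192 against 72 h 1 of 11 passed, the oxidative phosphorylation genes (mean difference 0.07, 16 of 25 positive, adjusted p 0.0279). Over all 1892 tested genes the median difference was -0.0737, and 36.3% were positive. By camera on the replicates of both times the list did not pass (adjusted p = 0.675 with an estimated correlation). It did not pass with only the correlation changed either (cameraPR, adjusted p 0.270), nor by fry (adjusted p 0.658).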

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

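Of the tests in this part, the comparison with lists of like intensity and the sign turns of the lists were set before their results were seen; the others were chosen after. The difference of the oxidative phosphorylation genes between 192 and 72 h, and the spots on prints 1 and 2, were also chosen after seeing the data.

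Oxidative phosphorylation genes had higher ratios at 192 h than at 72 h, by a mean of 0.0654 log2 over 25 genes (16 positive; cameraPR, adjusted p 0.0279). That test compares the list with the other genes, and the median difference over all 1892 tested genes was -0.0737, with 36.3% positive. By camera on the replicates of both times the list did not pass (adjusted p = 0.675 with an estimated correlation). With only the correlation changed the adjusted p was 0.270 by cameraPR. Fry, which tests the list against no change, gave an adjusted p of 0.658. The difference passed under 13 of 32 other settings and turned to -0.06 with the second scan only and to -0.03 on print 5 alone, with adjusted p between 0.000252 and 0.883. It did not pass without 72 h replicate 1 (mean 0.07) or 4 (0.03), or without 192 h replicate 1 (0.02) or 3 (0.05).

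The higher oxidative phosphorylation and hormone lists at 192 h did not pass by camera with an estimated correlation (adjusted p = 0.664 for both). For their means of 0.10 and 0.19 a trend with intensity is argued against. They lay at the 100th and 99.97th percentile of 10000 lists of like intensity, although those lists carry no correlation between genes. A difference between prints stays open, because the only 192 h replicate on print 5 had list means that differed by -0.0173 and 0.0810 from that of all genes, and print 5 and replicate cannot be told apart there. The 72 h replicate on print 4 differed by 0.0208 and 0.0775, below the 0.180 and 0.202 of the 192 h replicate on print 4. It is a single replicate, of poly(A) RNA on 1 named array with tumour in Cy5. The 192 h replicate is of total RNA on 2 arrays with dyes exchanged, so this contrast cannot argue against a difference between prints. Of the 4 sign turns of the 3 replicates, only the real one gave 2 lists and the highest other gave 1; 4 are too few for a share under 0.05. An effect of the tumour at this time may contribute and was not separately tested.

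The pair of arrays of 18 h replicate 3 with exchanged dyes correlated at -0.49 in Cy5 over Cy3, where 5 of the 7 such pairs were above 0. A difference between the 2 RNAs of this replicate gives a negative value, and a dye effect a positive one. Uneven hybridization between print blocks as the whole cause is argued against by a correlation of -0.29 that remained with loess within blocks. A tumour difference shared by the 18 h animals was not decided. This replicate correlated at -0.0260 with replicate 5 and at -0.135 with replicate 4. Those had usable ratios for only 18.3% and 37.6% of spots, and no pair of the same time correlated above 0.20. Such correlations therefore cannot argue against it. A difference particular to this pair of RNAs was not tested and stays open.

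Prints 1 and 2 gave intensities only weakly related to those of the other prints when matched by name (correlation 0.06 to 0.15). Failed hybridization was not decided: mean intensities on the 2 prints correlated at 0.75 by name and likewise at 0.75 by spot number. Signal tied to the spot and not to the RNA could give such a value. Names that belong to other spots are a candidate explanation. Accessions spotted at 2 places correlated at no more than -0.0269 there. Ribosomal protein probes had median intensity percentiles of 58.0 and 43.8 there, against 93.4 to 99.1 on prints 3 to 5. Oxidative phosphorylation probes had 67.0 and 66.1 against 91.3 to 97.2, so a complete mismatch of names is not shown. No biological explanation was tested.

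On the 13 arrays of prints 1 and 2, tested spot by spot without gene names, 50 of 7814 spots were lower at 18 h and none higher (limma, adjusted p 0.05; 6 replicates, 2 per time). At 72 h 1 of 8363 spots passed, at 192 h 0 of 7326, and over the 3 times 1 of 5358. By limma 916, 1423, 270 and 797 spots of these tests had an unadjusted p under 0.05. Tumour RNA was in Cy5 on every one of these arrays at 18 and 72 h, so tumour and dye cannot be separated in these counts.

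The counts of genes were 0 in every real comparison, so each sign turn or regrouping gave as many: 4 of 4 at 18, 72 and 192 h, and 100 of 100 drawn both over the 3 times (highest other 1) and between times (highest other 0). For the gene lists at 18 and 72 h the real count of 0 was likewise met by 4 of 4, with highest others of 0 and 1. With 4 turns no share under 0.05 can be reached.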

How the results depend on the processing

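Saturated spots kept, 2 replicates sufficing, spread over all measured genes, print 5 alone, the list tests between times and the list tests with only the correlation or only the replicates changed were chosen after seeing the data. Normexp and all 13 replicates were the planned main settings, and became alternatives after the data were seen; the other alternatives were planned as such. Over all settings, 2425 of 2473 values of 82 gene results kept their direction and their side of the threshold, 6 passed the test and 42 changed sign. This tally is partly fixed in advance and does not measure stability. No gene passed in the main fit, and leaving out a replicate of another time leaves the value of a time as it was. The genes named between times enter as F values, which have no sign. The oxidative phosphorylation list at 192 h passed in 23 of 32 settings (adjusted p 8.8e-09 to 0.955) and the hormone list in 16 of 32 (0.00997 to 0.955). Several of these 32 settings left the 192 h means as they were. In those without an 18 h or 72 h replicate only the estimated spread could change, so passing there adds little. The 32 leave out the other list tests. Of these, both lists passed with only the replicates changed. Neither list passed with fry, with an estimated correlation on the replicates of the time, or with only the correlation changed. Background-corrected signal divided by background, as a median over spots above 0 in both channels, lay between 0.703 and 20.1 on the named arrays. The alternative with poly(A) RNA only was not run, since 18 h has no named poly(A) replicate. Without replicate 1 or 3 at 192 h, with total RNA only and on print 5 alone there are fewer samples; for the other changes the cause was not tested.

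With normexp 9 genes passed at 72 h and 1 for 192 against 72 h. With RNA kind as a term 2 genes passed at 192 h and 1 list at 18 h, where no named replicate is of poly(A) RNA. By the authors' values 1 gene passed over the 3 times and 1 list at each time. Median centring gave 2 lists at 18 h, and no dye correction 1 list at 72 h. Of the 2 lists at 192 h, only the oxidative phosphorylation list passed with normexp (hormone list adjusted p 0.0635), median centring (0.0656), loess within print blocks, the first scan alone, the authors' values, saturated spots kept, all 13 replicates and without 18 h replicate 3 (0.0511), and only the hormone list with the third scan alone. With 2 replicates sufficing neither passed (adjusted p 0.0552 and 0.386), and the 1 list called there was another. The number of lists at 192 h was 0 with scale normalization, dye orientation as a covariate, total RNA only, the second scan alone, print 5 alone, camera with an estimated correlation, the estimated correlation with the main statistic, and fry, which does not compare a list with other genes. At an unadjusted p under 0.05 these settings had 4, 3, 2, 4, 0, 0, 2 and 1 lists, in this order. The number was 4 with the spread over all measured genes. Leaving out each of 9 replicates gave 0 to 4 lists at 192 h and 0 to 1 gene at 72 h. It gave Hcrt at 72 h from -0.20 to 0.11.

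Values that changed sign follow by setting, as log2 ratios. With normexp, Rps27 at 18 h -0.060, Rps6 at 18 h 0.021, Rps25 at 18 h 0.0014, Psmd4 at 72 h -0.0039, Hcrt at 72 h 0.16, Psmd13 at 192 h -0.15. With median centring, Rps27 at 18 h -0.061, Rpl37 at 18 h -0.33, Oxt at 18 h -0.16, Rps15 at 72 h -0.055, Hcrt at 72 h 0.028. With loess within print blocks, Sv2a at 72 h -0.17. With no dye correction, Mov10l1 at 72 h 0.11, Prokr1 at 72 h 0.060, Abat at 72 h 0.084. With dye orientation as a covariate, Tmem50b at 72 h -0.034, Mov10l1 at 72 h 0.16, Abat at 72 h 0.19, 3200001D21Rik at 192 h 0.56, Gpcpd1 at 192 h 0.029. With total RNA only, Hcrt at 72 h 0.11. With the second scan alone, oxidative phosphorylation genes at 192 h minus 72 h -0.057. With the third scan alone, Rps25 at 18 h 0.056, Rps15 at 72 h -0.093, Hcrt at 72 h 0.085, Psmc5 at 192 h -0.10. With the authors' value table, Rps27 at 18 h -0.017, Rps6 at 18 h 0.0014, Rpl37 at 18 h -0.076, Oxt at 192 h -0.0038. With print 5 alone, releasing and neurohypophysial hormones at 192 h -0.00065, oxidative phosphorylation genes at 192 h minus 72 h -0.032, Hcrt at 72 h 0.11, Cartpt at 192 h -0.0092, Hcrt at 192 h -0.047, Fosb at 192 h 0.10, Ndufs4 at 192 h -0.064, Scg3 at 192 h -0.034, Oxt at 192 h -0.12. With all 13 replicates by the given names, Top3a at 18 h -0.013, Lta4h at 18 h 0.060, Psmb6 at 72 h -0.053, Rpl24 at 72 h -0.19, Hcrt at 72 h 0.12.

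Whether replicate numbers pair the samples stays open. Across genes, 7 pairs of the same number at different times correlated at -0.0876 to 0.176, with 2 over 0.1. The 20 pairs of different numbers correlated at -0.215 to 0.106, with 1 over 0.1. With the replicate number as a block, 2 genes differed between times, Tmeff2 and Dbf4 (limma, adjusted p 0.0384 for both), and 6 genes for 192 against 18 h, while the oxidative phosphorylation list did not pass for 192 against 72 h (mean 0.03, adjusted p 0.0762).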
